A study of Mus musculus with 12 samples.

How the data were processed

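Transcript levels were measured in mouse embryonic fibroblasts (MEFs, primary connective tissue cells grown from mid-gestation embryos) of a mixed C57BL6/129Sv background on 12 Illumina MouseWG-6 BeadChip arrays, on which each probe reads 1 transcript sequence by hybridization of biotin-labelled cRNA. Per the labels, 4 genotypes were used: wild type (WT), Trex1 -/- (TKO), Sting -/- (SKO) and cells lacking both (STKO). STING, encoded by Sting1 (formerly Tmem173), is the adaptor through which cyclic GMP-AMP made by the cytosolic DNA sensor cGAS activates type I interferon genes. TREX1 is a cytosolic exonuclease that degrades DNA. Each genotype was given the vehicle DMSO or 20 µg/ml DMBA (7,12-dimethylbenz[a]anthracene, a polycyclic aromatic hydrocarbon carcinogen) for 24 or 48 h, with 1 array per genotype and treatment. The time of the DMSO cultures is not given in the sources used here, so DMBA and time in culture cannot be separated in any difference from DMSO.

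The signal file holds, per the file headers, a signal and a "Detection Pval" for each probe on each of 12 arrays. The deposited signal of a probe is an intensity on a linear scale, not normalized between arrays, and no background had been subtracted to around 0, since the lowest value per array was 38.7 to 47.9. The deposited detection column is a score per probe and array that ran against its name: its Spearman correlation with the signal was 0.98 to 0.99, so bright probes hold values near 1, and it was read as 1 minus the detection p. The authors' separate value table is in log2 units. It equals quantile-normalized log2 signals without background correction minus each probe's median over the 12 arrays, with a largest difference of 0.00125, and all 12 of its columns matched their own array best. The scanner and summary software are not given in the sources used here. Columns were tied to samples by the sample titles and descriptions, and 0 value columns were left without a sample.

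Signals were background corrected with a normal-exponential model that used the detection p, given an offset of 16, quantile normalized and put on a log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.01 on at least 2 of the 12 arrays were tested, which left 18389 probes. The annotation table paired 34885 probes of the array with 1 gene symbol, 18 with several and 10378 with none. Of the named probes, 34807 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez ID, which was used for gene names, neighbours and gene lengths only, and 0 symbols were updated. Among tested probes 15868 carried 1 gene, for 10142 distinct genes, of which 3911 had more than 1 tested probe. A gene was represented by its probe with the highest mean over the arrays, and other probes are described for genes where they pointed the other way or did not show a large difference. The text does not describe every other probe. The genome build of the probe design is not given in the sources used here, so no coordinates are printed. Signal medians per array were 69.8 to 87.5 and the highest signals 38277.3 to 48081.6. The number of arrays, not a count depth, limits the precision.

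Treatments were compared in a linear model with genotype and treatment as terms (limma lmFit and eBayes, 6 residual degrees of freedom), so that a treatment effect is the mean of 4 within-genotype differences and a genotype effect the mean of 3 within-treatment differences. The dependence of the DMBA response on STING, or on Trex1, was tested by adding the interaction of that status with treatment (4 residual degrees of freedom). A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes, 2-sided. Values after ± are limma's standard errors. The labels name no separate embryos or cultures, so the p-values measure only the spread of genotype-by-treatment differences between single arrays, which may be technical, and sex, position of origin and cell mix of a genotype's culture cannot be separated from its genotype. Genotype served as the block for treatments and treatment as the block for genotypes. The labels tie no 2 arrays to the same culture, so no closer pairing was made, and the file headers name no chip, so chip was not used as a block.

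The designs, the gene lists and the rule for named genes were fixed before the data were examined. For each comparison the rule takes the 10 probes with the largest rise and the 10 with the largest fall among called probes that moved the same way in every block (1 probe per gene), up to 4 called members of each list with the smallest p, the targeted genes, and the readouts Cyp1b1, Cdkn1a, Cxcl10, Ccl2, Ccl5, Il6, Ifnb1, Ifit1 and Isg15. Where fewer than 5 probes were called, the 5 list members with the smallest p are given as values. Genes outside the rule that make up a count of 5 or fewer are also named, and were chosen after their values were seen. The 22 lists were type I interferon-stimulated genes, cytokines and chemokines, NF-kB response genes, aryl hydrocarbon receptor targets, p53 targets, S phase, mitosis, NRF2 and oxidative stress, the integrated and ER stress response, extracellular matrix, matrix-degrading metalloproteinases, cholesterol synthesis, cytosolic DNA sensing, Hox genes, sex-linked genes, and markers of macrophages, endothelium, epithelium, neural cells, skeletal muscle, cartilage and adipocytes. Each list was tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 22 lists), and again with an estimated correlation. Median changes of a list on 1 array were ranked among 10000 random lists matched on brightness. Where a probe was undetected on all arrays of 1 group, a fold is given as "at least", computed after its values there were raised to the lowest value of any detected probe of the same array.

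The tests were checked on simulated data of 18389 probes for each comparison, with 100 probes changed by 1 and 100 by 2 on the log2 scale. For DMBA at 24 h the smaller change was recovered in 89% and the larger in 99%, at 48 h in 88% and 100%, for 48 against 24 h in 91% and 99%, and for the mean of both times in 95% and 100%. The Sting difference recovered 22% and 89%, and the Trex1 difference 18% and 98%. Recovery was 78% and 100% for TKO against WT, 77% and 98% for SKO against WT, 86% and 100% for STKO against TKO, 70% and 99% for STKO against SKO, and 43% and 95% for the Trex1 effect with minus without STING. False calls numbered 6 to 19 per comparison. Their share of the calls passed 5% in every comparison except DMBA at 24 h, TKO against WT and STKO against SKO, and was largest for the mean of both times, with 19 false among 214 calls. In these simulations the nominal 5% was therefore somewhat optimistic. Each was run once, with noise drawn independently for each probe. The spread was that of the model with genotype and treatment, also for the response differences. No correlation between probes and no spread between cultures was simulated, so recovery and false calls may differ in the real data. Alternatives were the authors' table, no background correction, median scaling, no detection filter, detection on all 12 arrays, a trended and robust variance, each genotype or treatment left out in turn, and for the response differences each time alone and both interaction terms. Plots were drawn with matplotlib 3.10.9 (python 3.11.15).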

Results

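Transcripts of mouse embryonic fibroblasts were measured on 12 bead arrays, 1 for each of 4 genotypes (WT, TKO, SKO and STKO) under each of 3 treatments (DMSO, DMBA for 24 h and DMBA for 48 h). Between 15662 and 16824 probes were detected per array (34.6 to 37.2% of the array's probes). The correlation of log2 values between any 2 arrays was 0.91 to 0.992 across probes. The first 3 principal components held 46.8, 16.8 and 11.1% of the variance. There was 1 array per genotype and treatment, so treatment effects have n = 4 genotypes, genotype effects n = 3 treatments, and single arrays have no replicate. All differences are on the log2 scale.

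The targeted transcripts separated the genotypes on every array. Sting1 read 7.80, 8.05 and 7.93 in WT under DMSO, 24 h and 48 h and 7.90, 8.12 and 7.97 in TKO, against 5.38, 5.52 and 6.01 in SKO and 5.06, 5.66 and 5.93 in STKO, and was detected in the latter 2 genotypes at 48 h alone. The main Trex1 probe read 8.62, 9.11 and 9.46 in WT and 8.12, 8.30 and 8.33 in SKO, against 6.45, 6.91 and 6.50 in TKO and 6.22, 6.50 and 7.19 in STKO. It was detected on all 12 arrays, a second Trex1 probe on the 6 WT and SKO arrays alone, and another on none. Ifnb1 and Ifit1, 2 of the planned readouts, were not detected on any array. Cxcl10 was detected on 5 of the 6 WT and TKO arrays (not in WT at 24 h) and on no SKO or STKO array. Ccl5 was detected on the 6 WT and TKO arrays and in SKO under DMSO. The Y-linked Eif2s3y read 9.62, 9.20 and 9.35 in WT and 4.39 to 4.52 on the other 9 arrays, while Xist was detected on all 12.

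What DMBA did to these cells on average over the 4 genotypes was asked first at 24 h. Cyp1b1, which encodes a cytochrome P450 that metabolizes polycyclic aromatic hydrocarbons and is induced through the aryl hydrocarbon receptor, rose by 0.97 ± 0.12 (adjusted p = 0.00256, higher in 4 of 4 genotypes). Nqo1, a quinone reductase induced by the same receptor and by NRF2, rose by 1.97 ± 0.24. The p53 target Cdkn1a, an inhibitor of cell cycle kinases, rose by 1.35 ± 0.19 and Trp53inp1 by 1.23 ± 0.15. Il6 rose by 1.19 ± 0.35 (adjusted p = 0.0459), while Cxcl10 (-0.23 ± 0.57), Ccl5 (0.06 ± 0.50), Ccl2 and Isg15 were not called. Under DMSO and at 24 h Il6 read 6.52 and 8.40 in WT, 6.06 and 7.84 in TKO, and 5.74 and 6.74 in SKO. In STKO it hardly moved, at 6.97 and 7.07. In all, 1251 probes rose and 1625 fell, for 2016 genes. The largest rises that pointed the same way in every genotype were 1700007K13Rik (3.93 ± 0.40), Espn (3.28 ± 0.43), Tnfrsf18, Svop, Bglap2, Ltb4r1, Anxa8 (2.81 ± 0.27), Cox6b2, Rln1 and Plek2. Tnfrsf18, a TNF receptor family member, was not well above background under DMSO and was at least 3.87-fold higher (means 7.62 and 4.44), and Svop at least 7.2-fold (8.51 and 5.37). The largest falls were Prkg1, a cyclic GMP-dependent kinase (-3.67 ± 0.41), Slc24a3 (-3.16), Gtdc1 (-3.03), Ldb2, Itga9, Piezo2, Pcdh9, Tenm3, Sema5a and Cyp7b1, and a second Pcdh9 probe read -0.43 without a call.

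By groups at 24 h, 6 of 7 aryl hydrocarbon receptor targets rose (7 adjusted over the list alone, median 1.04, camera adjusted p = 1.37e-05, adjusted p = 0.0682 with an estimated correlation). Of 23 p53 targets 15 rose and 1, Sesn1, fell (17 and 1 adjusted over the list alone; median 0.80, camera adjusted p = 7.64e-09, adjusted p = 0.341 with an estimated correlation). Of 14 NRF2 and oxidative stress genes 5 rose (9 adjusted over the list alone), led by Gsta4 (1.22 ± 0.11) and Srxn1. The list had median 0.60, camera adjusted p = 2.03e-05 and adjusted p = 0.0548 with an estimated correlation. NF-kB response genes rose in 5 of 16 cases (6 adjusted over the list alone), among them Icam1 (1.82 ± 0.39) and Ptgs2 (1.32 ± 0.34), with camera adjusted p = 0.00441 and adjusted p = 0.361 with an estimated correlation. Falls took 7 of 13 cholesterol synthesis genes (10 adjusted over the list alone; median -0.73, camera adjusted p = 2.72e-05), among them Fdps and Mvk, and 8 of 26 extracellular matrix genes (14 adjusted over the list alone; camera adjusted p = 0.000196), among them Tgfbi (-1.70 ± 0.33) and Col1a2. Both calls were lost at adjusted p = 0.361 with an estimated correlation. In the integrated and ER stress list Chac1 (-1.89 ± 0.26), Trib3, Xbp1 and 4 others of 18 fell while Atf3 rose by 2.05 ± 0.46 (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00441, adjusted p = 0.361 with an estimated correlation). Macrophage markers fell in 6 of 12 cases (9 adjusted over the list alone), led by C1qb (-1.49 ± 0.20), C1qc and Adgre1, with camera adjusted p = 2.14e-05 and adjusted p = 0.291 with an estimated correlation. Mitosis genes fell in 3 of 19 cases, Kif11, Kif23 (probes from -0.54 to 0.08) and Foxm1 (6 adjusted over the list alone; camera adjusted p = 0.00601, adjusted p = 0.634 with an estimated correlation), while 2 of 24 S phase genes, Ccne1 and Rrm2, rose, also when adjusted over the list alone. Of 31 cytokines and chemokines, Il6 and Tslp rose and 5 fell (6 and 9 adjusted over the list alone), and of 41 interferon-stimulated genes Tap1 (1.42 ± 0.15) and Irgm1 (1 of 3 probes called, from -0.06 to 0.51) rose and Ifi27l2a fell (1 rose adjusted over the list alone). The camera adjusted p was 0.743 for the cytokine list and 0.552 for the interferon list. Without WT, TKO or STKO the number of called probes was 729, 672 or 581 in place of 2876, and without SKO it was 3464. Some list shifts were small or absent in SKO. Against the DMSO array of the same genotype, the cholesterol median was -0.87 in WT, -1.19 in TKO, -0.71 in STKO and -0.13 in SKO. The integrated and ER stress median was -0.72, -0.78, -0.40 and -0.07 in the same order.

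At 48 h the same comparison called 3517 probes as risen and 3760 as fallen, for 4756 genes. The balance depended on scaling, with 4152 risen and 3076 fallen under median scaling. All 14 NRF2 genes rose (14 adjusted over the list alone, median 2.16, camera adjusted p = 7.2e-12, adjusted p = 0.00533 with an estimated correlation), with Gsta4 at 3.40 ± 0.11, Srxn1 at 2.76 ± 0.10, the glutathione synthesis subunit Gclm at 2.23 ± 0.15 and Txnrd1 at 2.08 ± 0.14. All 7 aryl hydrocarbon receptor targets rose as well (7 adjusted over the list alone; median 2.22, camera adjusted p = 1.08e-06, adjusted p = 0.049 with an estimated correlation), among them Nqo1 (4.10 ± 0.24), Gsta1 (at least 5.48-fold, means 8.12 and 4.58, not well above background under DMSO) and Cyp1b1 (1.49 ± 0.12). All 19 mitosis genes fell (19 adjusted over the list alone), among them Cdca3 (-1.54 ± 0.14), Foxm1 (-1.24 ± 0.14) and Birc5, a survivin gene. The list had median -0.99 and camera adjusted p = 6.16e-09. That call was lost at adjusted p = 0.357 with an estimated correlation. The largest rises in every genotype were Svop, Cox6b2, 1700007K13Rik, Espn, Tnfrsf18, Matn4, Gal, Akr1c18, Nqo1 and Mmp12 (3.95 ± 0.27). Svop was not well above background under DMSO and was at least 28.1-fold higher (means 10.47 and 5.37). The largest falls were Piezo2, a mechanically gated channel (-3.98 ± 0.37), Prkg1 (-3.79), Tgfbi (-3.65 ± 0.33), Slc24a3, Itga11, Aldh1l2, Tenm3, Cyp7b1, Cx3cr1 and Tril.

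Among cytokines and chemokines at 48 h 12 of 31 rose and 8 fell (13 and 8 adjusted over the list alone; median 0.44, camera adjusted p = 0.311). Ccl2 rose by 1.33 ± 0.30 (adjusted p = 0.00655) and Il15 by 1.21 ± 0.19. Cxcl12 fell by 2.47 ± 0.44. Il6 was called (adjusted p = 0.0355) although its differences were 2.2 in WT, 1.88 in TKO, 0.20 in SKO and -0.05 in STKO. Cxcl10 (0.34 ± 0.57, adjusted p = 0.666), Ccl5 (0.73 ± 0.50, adjusted p = 0.27) and Isg15 (0.48 ± 0.29, adjusted p = 0.22) were not called over the 4 genotypes. Interferon-stimulated genes rose in 11 of 41 cases and Ifi27l2a fell (8 and 1 adjusted over the list alone), with Tap1 at 1.59 ± 0.15 and Gbp3 at 1.27 ± 0.17, median 0.35, camera adjusted p = 0.00807 and adjusted p = 0.668 with an estimated correlation. Of 16 NF-kB response genes 7 rose and Saa3 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0305, adjusted p = 0.54 with an estimated correlation), including Ptgs2 at 2.15 ± 0.34.

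In the p53 list 18 of 23 rose at 48 h (18 adjusted over the list alone; median 0.91, camera adjusted p = 1.81e-08, adjusted p = 0.357 with an estimated correlation). Trp53inp1 rose by 1.72 ± 0.15, Polk by 1.59 ± 0.17 and Phlda3 by 1.51. S phase genes fell in 14 of 24 cases (14 adjusted over the list alone; camera adjusted p = 0.003, adjusted p = 0.635 with an estimated correlation), including Chaf1a at -0.78 ± 0.12. Cholesterol synthesis genes fell in 12 of 13 (12 adjusted over the list alone; median -1.36, camera adjusted p = 3.16e-06, adjusted p = 0.403 with an estimated correlation). Fdps stood at -2.10 ± 0.22 and Cyp51 at -1.49 ± 0.15. In the extracellular matrix list 15 of 26 fell, Tgfbi and Col5a1 (-1.19 ± 0.17) among them, and Dcn (1.32 ± 0.14) and Timp1 rose (15 and 2 adjusted over the list alone; camera adjusted p = 0.00286, adjusted p = 0.54 with an estimated correlation). Of 18 integrated and ER stress genes 11 fell, with Chac1 at -2.72 ± 0.26, Asns at -1.64 ± 0.17 and Xbp1 at -1.35, and Atf3 and Dnajb9 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00298, adjusted p = 0.357 with an estimated correlation). The macrophage markers C1qa (-1.98 ± 0.17), C1qb, C1qc and 4 others fell while Lyz2 (0.93 ± 0.13), Tyrobp and Lyz1 rose, the same number adjusted over the list alone (camera adjusted p = 0.109).

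The other lists had no camera call at 48 h. Metalloproteinases had 2 rises and 4 falls among 9, with a median of -0.58, a mean of 0.24 and camera adjusted p = 0.768. Cytosolic DNA sensing genes had 5 rises, among them Dnase2a (0.69 ± 0.15), and 2 falls among 17, with adjusted p = 0.169. The 5 include both targeted genes. Trex1 differed by 0.84, 0.05, 0.21 and 0.96 in WT, TKO, SKO and STKO. Sting1 differed by 0.13 in WT and 0.07 in TKO and was undetected under DMSO in SKO and STKO, so no exact rise can be given there. Endothelial markers had 1 rise and 2 falls of 4 (adjusted p = 0.62), epithelial markers 2 rises of 7, Krt19 and Cdh1 (adjusted p = 0.561), and neural markers a rise of Nes and a fall of Map2 (adjusted p = 0.768). Skeletal muscle markers had a rise of Tnnc1 and a fall of Acta1 (adjusted p = 0.879), adipocyte markers a rise of Cebpa and a fall of Pparg (adjusted p = 0.896), and Hox genes 2 rises and 5 falls of 23 (adjusted p = 0.76). Cartilage markers, with a rise of Matn4 and falls of Col11a1 and Sox9, had a median of -0.43 and a mean of 0.60 (adjusted p = 0.62). Among sex-linked genes Xist alone rose, by 0.89 ± 0.11, and the list's median was -0.11, its mean 0.10 (adjusted p = 0.768). The counts adjusted over the list alone were the same for all of these lists.

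**Figure D1:**
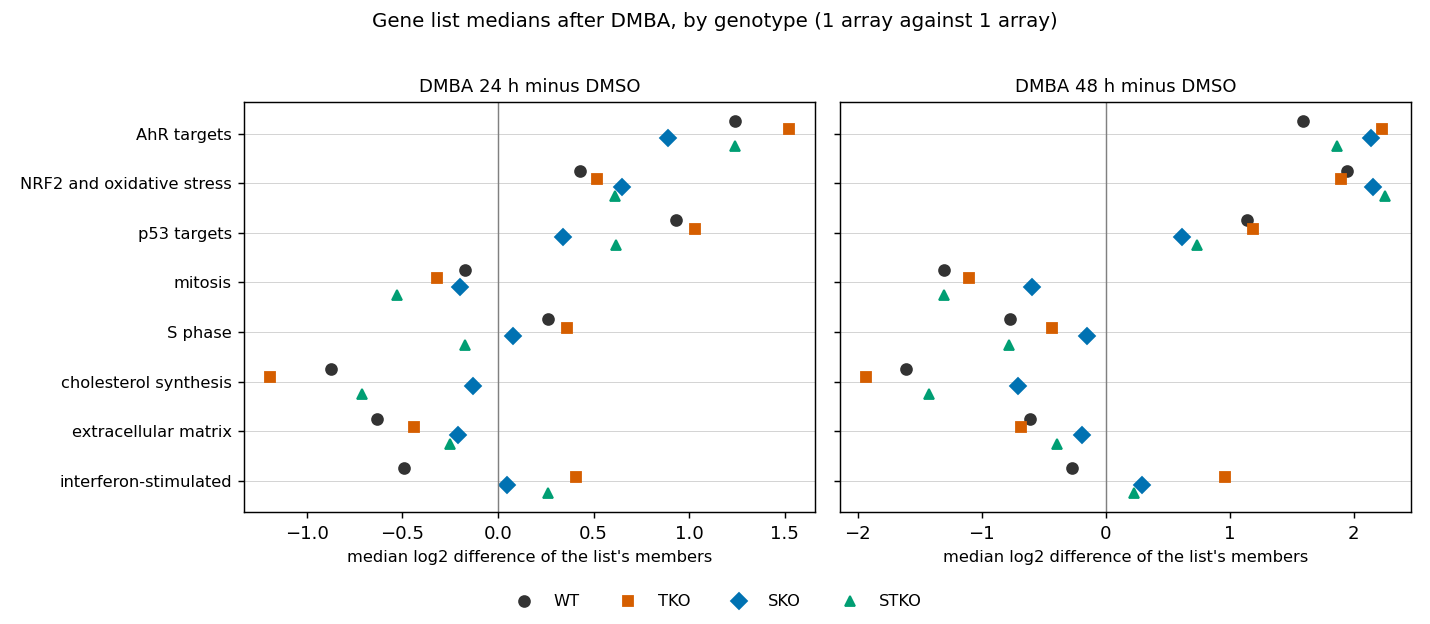
Median log2 difference of list members from the DMSO array of the same genotype, at 24 and 48 h of DMBA, for 8 gene lists. There is 1 marker per genotype, and each point sets 1 DMBA array against 1 DMSO array. The interferon-stimulated median reached 0.96 in TKO at 48 h and -0.27 in WT.

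Which changes grew or faded between 24 and 48 h was asked by differences that use no DMSO array, although the DMSO arrays enter the residual spread of the fit. NRF2 genes rose further in 12 of 14 cases (14 adjusted over the list alone), with Gsta4 at 2.18 ± 0.11, Srxn1 at 2.06 ± 0.10 and Gclm at 1.95 ± 0.15. The list moved with camera adjusted p = 4.92e-17 and adjusted p = 0.00191 with an estimated correlation. Mitosis genes fell in 15 of 19 (18 adjusted over the list alone; camera adjusted p = 2.27e-12, adjusted p = 0.35 with an estimated correlation), Cdca3 by 1.37 ± 0.14. S phase genes fell in 13 of 24 (19 adjusted over the list alone; camera adjusted p = 8.92e-11, adjusted p = 0.351 with an estimated correlation), Chaf1a by 0.84 ± 0.12. Of 7 aryl hydrocarbon receptor targets 6 rose (6 adjusted over the list alone; camera adjusted p = 1.33e-06, adjusted p = 0.0507 with an estimated correlation). Cholesterol synthesis genes fell further in 6 of 13 (8, with 1 rise, adjusted over the list alone; camera adjusted p = 2.88e-05, adjusted p = 0.562 with an estimated correlation). In the p53 list Tnfrsf10b fell (probes from -0.62 to 0.12) and no gene rose (0 adjusted over the list alone), at camera adjusted p = 0.00178 upward and adjusted p = 0.703 with an estimated correlation. The interferon list gained Gbp3 and Lgals3bp (2 adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.724 with an estimated correlation). Cytokines had 5 rises and 1 fall (7 and 1 adjusted over the list alone; camera adjusted p = 0.0293), and the integrated stress list 1 rise and 5 falls (1 and 6 adjusted over the list alone; camera adjusted p = 0.0169), both at adjusted p = 0.562 with an estimated correlation. The largest rises were Akr1c18 (3.33), the cystine transporter Slc7a11 (2.95 ± 0.30), Mcpt8, Mmp3, Gsta3, Gal, Cox6b2, Gsta1, Gsta2 and Mmp12. The largest falls were Aldh1l2 (-2.44), Tgfbi, C1qtnf3, Ccn5, Aqp1, Bcat1, Mfsd2a, Bok (-1.54 ± 0.11), Cdkn3 and Mylk. Of 3 tested Aldh1l2 probes 2 were called. In all 961 probes rose and 958 fell, and without WT, TKO or STKO the total was 460, 589 or 170.

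Over the mean of both times, which serves to compare the real assignment of controls with others, 3107 probes rose and 3325 fell (3310 and 2854 with median scaling). 1700007K13Rik (4.23 ± 0.35), Svop and Cox6b2 (3.87) rose most, and Mdm2, the p53 target that degrades p53, rose by 2.05 ± 0.22. All 14 NRF2 genes (14 adjusted over the list alone; camera adjusted p = 3.06e-10, adjusted p = 0.00804 with an estimated correlation) and all 7 aryl hydrocarbon receptor targets (7 adjusted over the list alone; camera adjusted p = 1.26e-06, adjusted p = 0.0502 with an estimated correlation) rose. Of 23 p53 targets 18 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 5.3e-09), 16 of 19 mitosis genes fell (16 adjusted over the list alone; camera adjusted p = 4.73e-07), and 11 of 13 cholesterol genes fell (12 adjusted over the list alone; camera adjusted p = 2.73e-06), all 3 at adjusted p = 0.365 with an estimated correlation. Without WT, TKO or STKO the 6432 called probes became 3928, 3670 or 3931.

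The series asks about cytokine production after DMBA and the part of STING in it, so the DMBA response of WT and TKO was compared with that of SKO and STKO. The Il6 response was greater with STING by 1.62 ± 0.25 (adjusted p = 0.0192), being 2.04 in WT, 1.83 in TKO, 0.60 in SKO and 0.02 in STKO. Il11, a cytokine of the Il6 family, was greater in both genotypes with STING (2.71 and 2.56, against 0.55 and 0.80; adjusted p = 0.0134). Ccl5 was called at an adjusted p of 0.0496, with 0.87 in WT and 1.99 in TKO. It was undetected on every STKO array and on the SKO arrays after DMBA, so those 2 genotypes give no response that can be read. Cxcl10 moved by 2.14 in TKO and was not called (adjusted p = 0.978). In WT it read 8.15 under DMSO, was undetected at 24 h and read 6.64 at 48 h. It was undetected on every SKO and STKO array, so its dependence on STING cannot be read from this difference. Nor were Isg15 (-0.29, adjusted p = 0.719), Ccl2 (0.55, adjusted p = 0.385) or Cyp1b1 (-0.23, adjusted p = 0.442) called. In all, 536 probes responded more positively with STING and 586 more negatively, for 857 genes. The largest positive differences were Tnfrsf18, Bglap2, Bglap, Crct1, Ltb4r1, Ckmt1, Akr1c18, Evpl, Atg9b and Ccno. The largest negative ones were Atrnl1, Itga11, Itgbl1 (-2.98 ± 0.22), Col8a2, Babam2, Fggy, Slc39a11, Cyp7b1, Cldn11 and Rbms3, and Atrnl1 and Cldn11 were detected on 2 arrays only, so that most of their values lie at background.

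Of 23 p53 targets 5 responded more with STING (9 adjusted over the list alone), namely Pmaip1 (2.06 ± 0.33), Ccng1, Plk3, Aen and Cdkn1a (0.82 ± 0.19), with camera adjusted p = 3.45e-05. For Ccng1 and Aen 1 of 3 probes each was called. Cholesterol synthesis genes fell more with STING in 2 of 13 cases, Fdps and Sc5d (7 adjusted over the list alone; camera adjusted p = 3.45e-05), and in the extracellular matrix list Postn (detected on 1 of 3 arrays each in WT and TKO), Col1a2 and Col5a2 were more negative and Timp1 and Ccn2 more positive (10 and 2 adjusted over the list alone; camera adjusted p = 0.000836). The calls of all 3 lists were lost at adjusted p = 0.857 with an estimated correlation. Of 41 interferon-stimulated genes Ifi27l2a alone was called, being more negative with STING (1 adjusted over the list alone; median -0.12, camera adjusted p = 0.481). This says little about the list, because 14 of the 41 were undetected on every SKO and STKO array and have no readable response there. It also averages over WT and TKO, whose medians moved in opposite directions (-0.49 and 0.41 at 24 h, -0.27 and 0.96 at 48 h). In the cytokine list 3 of 31 were more positive and Il18 more negative (4 and 2 adjusted over the list alone; camera adjusted p = 0.481), and in the NF-kB list Cd40 (1.52 ± 0.24) and Ptgs2 were more positive (5 adjusted over the list alone; camera adjusted p = 0.0757). Aryl hydrocarbon receptor targets had 1 call, Nqo1 (1 adjusted over the list alone; median -0.08, mean 0.20, camera adjusted p = 0.575), and a second Nqo1 probe read 0.05. In the NRF2 list Gstm1 was more negative on 1 probe (-0.85) but not on another (0.36; 2 adjusted over the list alone; camera adjusted p = 0.47). The count of 1122 became 23, 16, 0 or 656 without WT, TKO, SKO or STKO, fits that leave 1 genotype standing for its STING status, and 211 without a detection filter.

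Whether Trex1 status changed the DMBA response was asked in the same way. Limma called 0 probes (290 at an unadjusted p under 0.05). With both interaction terms it also called 0, with 1257 at an unadjusted p under 0.05. The fit with the Trex1 term alone, used below, keeps the Sting difference in its spread. Its median standard error was 0.27, against 0.183 for the Sting difference. The lack of calls is therefore no evidence of an equal response. The 5 list members with the smallest p, each with an adjusted p of 1, were Gbp3 (0.70 ± 0.23), Cxcl16 (0.93 ± 0.34), Rsad2 (1.90 ± 0.72), Cxcl10 (2.12 ± 0.82) and Cd14 (0.99 ± 0.39), all more positive without Trex1. The Cxcl10 value comes from WT and TKO, since the other 2 genotypes lay at background, as did WT at 24 h. Rsad2, an interferon-stimulated antiviral enzyme, moved by -1.60 in WT and 2.16 in TKO and was likewise undetected on every SKO and STKO array. As a list, the 41 interferon-stimulated genes were shifted upward without Trex1 (median 0.54, camera adjusted p = 9.38e-19), as were NF-kB genes (0.31, adjusted p = 0.000101), cytokines (0.32, adjusted p = 0.000872) and macrophage markers (0.31, adjusted p = 0.00159), with 0 members called in each adjusted over the list alone. All 4 were at adjusted p = 0.376 with an estimated correlation. Since 14 of the 41 interferon-stimulated genes were undetected on every SKO and STKO array, their part of that shift comes from WT and TKO. Against the DMSO array of its genotype the list's median at 24 and 48 h was -0.49 and -0.27 in WT and 0.41 and 0.96 in TKO. In SKO it was 0.05 and 0.29 and in STKO 0.26 and 0.23. The shift therefore lay mostly between WT and TKO. Cholesterol (-0.49, adjusted p = 5.85e-05) and mitosis genes (-0.25, adjusted p = 9.61e-05) were shifted downward, at adjusted p = 0.618 with an estimated correlation, p53 targets upward (0.15, adjusted p = 0.0102; adjusted p = 0.759 with an estimated correlation) and S phase genes downward (-0.12, adjusted p = 0.0318; adjusted p = 0.767 with an estimated correlation).

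What loss of Trex1 did in cells with STING was asked by TKO against WT over the 3 treatments. Interferon-stimulated genes were higher in TKO in 24 of 41 cases and lower in none (36 adjusted over the list alone; median 1.09, camera adjusted p = 1.17e-26, adjusted p = 0.134 with an estimated correlation). Oasl1 was higher by 3.33 ± 0.51, Trim30a by 2.85 ± 0.32 and Irf7 by 1.97 ± 0.26. Isg15, a ubiquitin-like interferon product, was higher by 1.63 under DMSO, 2.84 at 24 h and 2.65 at 48 h. The chemokine Cxcl10 was higher by 3.47 ± 0.66 (adjusted p = 0.0127), made up of 0.73 under DMSO, 4.63 at 24 h (undetected in WT) and 5.05 at 48 h, and Ccl5 was higher by 3.37, 3.98 and 4.99. Il6 (adjusted p = 0.604) and Ccl2 (adjusted p = 0.819) were not called. In all 409 probes were higher and 549 lower in TKO, for 683 genes. Beside Ccl5, Cxcl10, Oasl1 and Trim30a the largest rises were Plk1, Gpr149 (3.85 ± 0.22; a second probe read -0.04), Sim2 (at least 8.55-fold, means 8.76 and 4.92, not well above background in WT), Igfbp5, Bcl11b and St3gal6. The largest falls were the Y-linked Eif2s3y (at least 12.7-fold, means 4.42 and 9.39, not well above background in TKO), Gbp2b, Rpl29, Epm2aip1 (probes from -4.46 to 0.82), Serpina3n, Tm7sf3, Mfap5, Mmp12, Npy and Lyz2 (-2.97 ± 0.15).

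Macrophage markers were lower in TKO in 10 of 12 cases (11 adjusted over the list alone; median -2.51, camera adjusted p = 1.45e-24, adjusted p = 0.0208 with an estimated correlation). Tyrobp stood at -2.55 ± 0.13, Fcer1g at -2.53 ± 0.12 and Laptm5 at -2.50 ± 0.17. Sex-linked genes were lower in 3 of 4 (3 adjusted over the list alone; camera adjusted p = 1.99e-07, adjusted p = 0.0208 with an estimated correlation), including Xist (-0.69 ± 0.13). Of 31 cytokines 3 were higher, among them Cxcl14 (2.53 ± 0.21), and 4 lower, among them Ccl3 (7 and 10 adjusted over the list alone; median -0.22, mean 0.06, camera adjusted p = 0.246). S phase genes were shifted upward with Rrm2 alone called (0 adjusted over the list alone; camera adjusted p = 7.47e-07, adjusted p = 0.283 with an estimated correlation), and mitosis genes with Plk1 alone (1 adjusted over the list alone; camera adjusted p = 0.000128, adjusted p = 0.415 with an estimated correlation). The neural markers Map2 (1.76 ± 0.26) and Stmn2 were higher (2 adjusted over the list alone; camera adjusted p = 0.00641, adjusted p = 0.134 with an estimated correlation). Epithelial markers, with Krt18 called (2 adjusted over the list alone), had camera adjusted p = 0.0124 and adjusted p = 0.166 with an estimated correlation. Adipocyte markers had camera adjusted p = 0.0124 downward and adjusted p = 0.175 with an estimated correlation (0 called, 2 adjusted over the list alone), and the NRF2 list camera adjusted p = 0.0229 downward and adjusted p = 0.144 with an estimated correlation (0 called, 0 adjusted over the list alone). Among Hox genes, whose expression records position along the body, Hoxd10 (0.73 ± 0.12), Hoxd13 and Hoxb9 were higher and Hoxb3 (-1.08 ± 0.20) and Hoxd3 lower. The 958 called probes became 303 without the 24 h arrays, 405 without the 48 h arrays and 509 when detection on all 12 arrays was required.

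**Figure D2:**
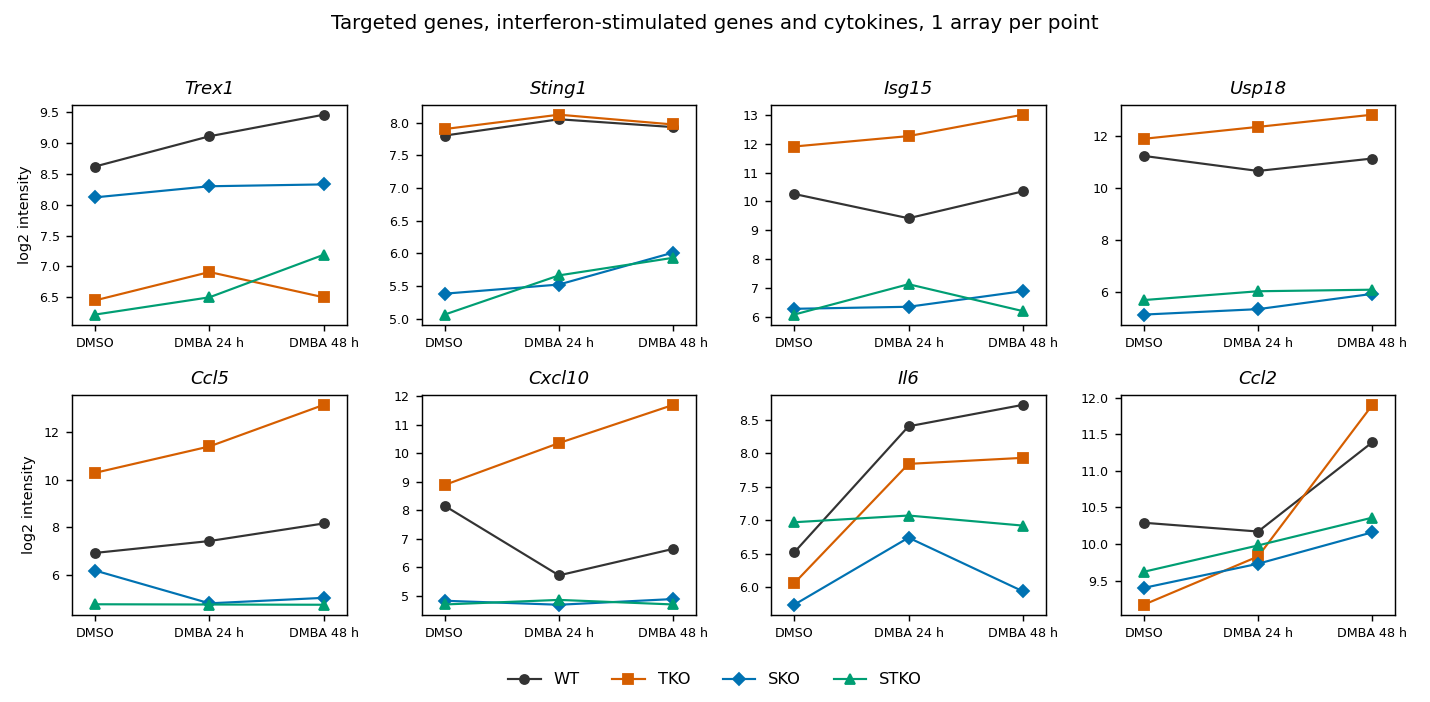
Log2 intensity of Trex1, Sting1, Isg15, Usp18, Ccl5, Cxcl10, Il6 and Ccl2 on each of the 12 arrays, over DMSO, DMBA 24 h and DMBA 48 h, with 1 line per genotype, no replicates, and vertical axes that differ between panels and do not start at 0. Cxcl10 read 8.88, 10.35 and 11.69 in TKO, 8.15, 5.71 and 6.64 in WT, and 4.68 to 4.88 in SKO.

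What loss of STING did in cells with Trex1 was asked by SKO against WT. Interferon-stimulated genes were lower in 30 of 41 cases and higher in none (34 adjusted over the list alone; median -1.70, camera adjusted p = 6.33e-32, adjusted p = 0.169 with an estimated correlation). Usp18, a negative regulator of interferon signalling, stood at -5.56 ± 0.21, Oasl2 at -4.07 ± 0.42, Gbp3 at -3.70 ± 0.20 and Isg15 at -3.49 ± 0.34. Il6 was lower by 1.74 ± 0.40 (adjusted p = 0.0315), with 0.78, 1.66 and 2.79 under DMSO, 24 h and 48 h, and Il15 by 1.89 ± 0.22. Cxcl10, not well above background in SKO (at least 2.17-fold lower, means 4.79 and 6.83), was not called (adjusted p = 0.104). Ccl5 (-2.16 ± 0.57, adjusted p = 0.0546) was not called either, and in SKO was detected under DMSO alone. In all, 522 probes were higher and 681 lower in SKO, for 853 genes. The largest rises were Nnmt, Gpr149, Erdr1 (at least 9.22-fold, means 8.87 and 4.56), Igfbp5, Flt1 (3.21 ± 0.17), Bcl11b, Itga11, Sema5a, Ptprv and Galnt18, and a second Gpr149 probe read 0.06. The largest falls were Zfp330 (at least 46.8-fold, means 4.72 and 11.27, not well above background in SKO), Usp18, Mcm6, Eif2s3y, Rpl29, Me1, Oasl2, Gbp3, Gvin1 and Rsad2. A second Zfp330 probe read -0.34, and other Mcm6 probes reached 0.02.

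The cytokine list had 2 genes higher and 3 lower in SKO (3 and 11 adjusted over the list alone; camera adjusted p = 0.0665). NF-kB genes were lower in 5 of 16 (7 adjusted over the list alone; camera adjusted p = 0.00155, adjusted p = 0.397 with an estimated correlation). Aryl hydrocarbon receptor targets were lower in 3 of 7, Xdh, Ugt1a6a and Cyp1b1 (-0.88 ± 0.14; 4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0018). Cytosolic DNA sensing genes were lower in 4 of 17, Sting1 (-2.29 ± 0.17, detected in SKO at 48 h alone), Ifi204 (-1.64 ± 0.23), Trex1 (-0.82 ± 0.20) and Adar (4 adjusted over the list alone; camera adjusted p = 0.02), and sex-linked genes in 2 of 4 (2 adjusted over the list alone; camera adjusted p = 0.00305). These last 3 lists were at adjusted p = 0.169 with an estimated correlation. Macrophage markers were lower in 3 of 12, Fcer1g (-0.55 ± 0.12), Lyz2 and Laptm5 (5 adjusted over the list alone; camera adjusted p = 0.00543, adjusted p = 0.477 with an estimated correlation). Extracellular matrix genes were higher in 6 of 26 and Dcn lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.00989), cholesterol genes higher with Lss called on 1 of 2 probes (0.94 and -0.22; 3 adjusted over the list alone; camera adjusted p = 0.000372), and mitosis genes with Foxm1 (0 adjusted over the list alone; camera adjusted p = 0.000909), each at adjusted p = 0.484 with an estimated correlation. S phase genes had 0 calls (0 adjusted over the list alone; camera adjusted p = 0.00305, adjusted p = 0.485 with an estimated correlation). Hoxa5 was lower by 1.39 ± 0.16 and Hoxb9 higher by 1.01 ± 0.12. The 1203 called probes became 2168 without the DMSO arrays, 208 without the 24 h arrays, 421 without the 48 h arrays and 754 with detection required on all 12.

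Whether the high interferon-stimulated transcripts of Trex1-deficient cells needed STING was asked by STKO against TKO. Ccl5 was at least 56.7-fold lower in STKO (means 4.75 and 11.61), Rsad2 at least 39.9-fold (5.05 and 11.10), Cxcl10 at least 22.9-fold (4.74 and 10.30) and Trim30a at least 20.0-fold (4.50 and 10.11), all not well above background in STKO. Usp18 was lower by 6.44 ± 0.21, Oasl2 by 6.28 ± 0.42 and Ifit3 by 4.98 ± 0.41. In the interferon list 37 of 41 were lower and none higher (39 adjusted over the list alone; median -2.74, camera adjusted p = 7.9e-63, adjusted p = 0.0396 with an estimated correlation). Il6 (-0.29, adjusted p = 0.804) and Ccl2 (-0.32, adjusted p = 0.739) were not called. In all 436 probes were higher and 455 lower, for 634 genes. Isg15, Oasl1 and Oas1g completed the 10 largest falls, and the largest rises were Nnmt (at least 20.2-fold, means 10.05 and 5.25), Erdr1, the myeloid lectin Clec4n (3.52 ± 0.28), Tm7sf3, Fcrls, Adgre1, C1qc (2.90 ± 0.22), C1qb, Pf4 and Ms4a7. A second Erdr1 probe read 0.30.

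Macrophage markers were higher in STKO than in TKO in 10 of 12 cases (12 adjusted over the list alone; median 2.19, camera adjusted p = 4.97e-22, adjusted p = 0.0298 with an estimated correlation), Lyz2 by 2.46 ± 0.15 and Fcer1g by 2.19 ± 0.12. Of the cytokines Ccl9 (2.24 ± 0.30) and Ccl3 were higher and Ccl5, Cxcl10 and Il33 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.838). Neural markers were lower in 3 of 4 (3 adjusted over the list alone; camera adjusted p = 0.00133, adjusted p = 0.0657 with an estimated correlation). Epithelial markers were lower in 2 of 7 (3 adjusted over the list alone; camera adjusted p = 0.0135) and DNA sensing genes in 4 of 17, with Sting1, detected in STKO at 48 h alone, at -2.45 ± 0.17 (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0328), both at adjusted p = 0.173 with an estimated correlation. Cholesterol genes (camera adjusted p = 0.0176, upward, 0 called), S phase genes (camera adjusted p = 0.0127, downward, 0 called), mitosis genes (camera adjusted p = 0.0176, downward, Plk1 called) and extracellular matrix genes (camera adjusted p = 0.046, upward, 4 higher and 2 lower) were all at adjusted p = 0.642 with an estimated correlation. Adjusted over the list alone, these 4 lists had 0, 0, 1 lower, and 6 higher with 3 lower. Xist was higher by 0.98 ± 0.13 and Hoxa5 lower by 1.44 ± 0.16. The 891 called probes became 294 without the 24 h arrays, 494 without the 48 h arrays and 460 with detection required on all 12.

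What loss of Trex1 did in cells without STING was asked by STKO against SKO. Trex1 itself was lower by 1.61 ± 0.20 on its main probe. On the second it was at least 2.84-fold lower (means 5.45 and 7.29, not well above background in STKO). Of 41 interferon-stimulated genes 0 were called by limma (0 adjusted over the list alone; median -0.06, camera adjusted p = 0.72), with Isg15 at -0.04 ± 0.34 (adjusted p = 0.989), and 14 of the 41 were undetected on all 6 arrays. Cxcl10 was undetected on all 6 arrays and Ccl5 on all but SKO under DMSO. No difference between SKO and STKO over the 3 treatments can therefore be read for them. In all 15 probes were higher and 19 lower, for 24 genes. The rises were Zfp330 (at least 25.4-fold, means 10.38 and 4.72, not well above background in SKO), Mcm6, Twistnb (3.32 ± 0.12), Map4k5, Ccng2 (1.89 ± 0.13), Anxa4, Mgll, Usp38 and Hoxb4. Beside Trex1 the largest falls were Epm2aip1, Lars2 (-3.22 ± 0.16), Sema3f, the growth factor Bmp4, Casp4, Gbp2b, Tbx4, Timmdc1 and Ctsc. Other probes of Zfp330 (0.23), Mcm6 (down to -0.15), Anxa4 (-0.15), Map4k5 (0.32), Usp38 (0.28) and Epm2aip1 (up to 0.67) did not show these differences. For Mgll, Casp4 and Ctsc 1 probe each was called and the others pointed the same way. Mitosis genes were shifted downward without a called member (0 adjusted over the list alone; camera adjusted p = 0.000811), as were cholesterol and integrated stress genes, and skeletal muscle markers upward (adjusted p = 0.0272 each). The extracellular matrix list was shifted downward and macrophage markers upward (adjusted p = 0.0426 each), and all 6 were at adjusted p = 0.639 with an estimated correlation. Of these, 1 extracellular matrix gene was called adjusted over the list alone. The 34 called probes became 74 without the DMSO arrays, 9 without the 24 h arrays, 11 without the 48 h arrays and 18 with detection required on all 12.

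The dependence of the Trex1 effect on STING was tested directly, as the TKO to WT difference minus the STKO to SKO difference. A trait of 1 genotype's culture alone also enters this difference and cannot be told from such dependence. Eif2s3y was detected on the WT arrays alone. Macrophage markers stood lowest in TKO, at -2.61, -2.98 and -2.80 relative to WT under DMSO, with SKO and STKO between -0.50 and -1.39. Ccl5 differed by 4.70 ± 0.81 (adjusted p = 0.0116), Isg15 by 2.41 ± 0.48 (adjusted p = 0.025), Trim30a by 2.84 ± 0.45 and Irf7, the transcription factor that amplifies interferon production, by 2.06 ± 0.37, each positive in 3 of 3 treatments. Cxcl10 was not called (3.52 ± 0.94, adjusted p = 0.0939). For Ccl5, Cxcl10, Trim30a and Irf7 the STKO to SKO part lay at or near background. In the interferon list 7 of 41 were called, all positive (30 adjusted over the list alone; median 1.11, camera adjusted p = 4.49e-21, adjusted p = 0.214 with an estimated correlation). Macrophage markers were negative in 10 of 12 (11 adjusted over the list alone; median -2.70, camera adjusted p = 1.06e-23, adjusted p = 0.0237 with an estimated correlation), Lyz2 by -3.09 ± 0.21. Sex-linked genes were negative in 2 of 4 (3 adjusted over the list alone; camera adjusted p = 8.81e-07, adjusted p = 0.0279 with an estimated correlation). Mitosis genes were shifted upward with Plk1 called (2 adjusted over the list alone; camera adjusted p = 3.58e-07, adjusted p = 0.367 with an estimated correlation), S phase genes with 0 called (0 adjusted over the list alone; camera adjusted p = 1e-06, adjusted p = 0.369 with an estimated correlation), and neural markers with Map2 and Stmn2 called (2 adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.214 with an estimated correlation). In all 209 probes were positive and 339 negative, for 411 genes. The largest positive differences beside Ccl5 were Plk1 (detected on 1 of 3 arrays each in WT and STKO), Sim2, Bmp4, Tbx4, Ctsc, Gpr149, Oasl1, Sema3f and Itih2. The largest negative ones were Zfp330, Eif2s3y, Rpl29, Cck, Mmp12, Mcm6, Anxa4, Tm7sf3, Nkx2-3 and Fcgr3. On another probe of the same gene Zfp330 read -0.25, Rpl29 -0.89, Anxa4 -0.12, Gpr149 -0.28 and Mcm6 up to 0.55. The 548 called probes became 110 without the 24 h arrays, 193 without the 48 h arrays and 244 with detection required on all 12.

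Single arrays were compared without a test. In TKO the median of the interferon-stimulated genes stood 0.41 above its own DMSO array at 24 h and 0.96 at 48 h, each above all 10000 random lists. In WT it stood at -0.49 at 24 h, below all random lists, and at -0.27 at 48 h (percentile 1.66). In SKO it stood at 0.05 at 24 h (percentile 87.4) and 0.29 at 48 h (percentile 99.95). In STKO it stood at 0.26 at 24 h (percentile 99.97) and 0.23 at 48 h (percentile 99.07). The medians of SKO and STKO include 14 genes undetected on all their arrays. The members that moved most in TKO at 48 h were Rsad2 (2.67), Oasl1 (2.22) and Cmpk2 (2.18), and in WT at 24 h Ifi27l2a (-1.87), Rsad2 (-1.75) and Cmpk2 (-1.74). Under DMSO alone the list stood 0.42 above WT in TKO and at -2.13 and -2.29 in SKO and STKO. Ccl5 read 10.29, 11.40 and 13.15 in TKO and 6.92, 7.42 and 8.16 in WT, and Ccl2 read 9.17, 9.83 and 11.90 in TKO and 10.29, 10.17 and 11.39 in WT. Probes at least 2-fold above or below their own DMSO array at 48 h numbered 1547 and 1555 in WT, 1541 and 1501 in TKO, 618 and 459 in SKO, and 1046 and 964 in STKO.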

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

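The comparison of the whole response with that of the aryl hydrocarbon receptor and NRF2 lists, and the comparison of SKO with STKO, were tests chosen only after the result was seen.

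The DMBA response differed with STING status at 1122 probes, tested as an interaction. The dependence of the Trex1 effect on STING, also tested as an interaction, was called at 548 probes. A trait of 1 genotype's culture alone can also give a call there. For the first, 1 of the 3 ways to pair the 4 genotypes called as many probes, the real one, and the highest other called 0. For the second 2 of 3 did so. The highest other, with 1792, set the genotypes with STING against those without, and the remaining one, with 432, did so for Trex1. Both are effects in themselves, so they are no null for it. So few splits cannot give a share under 0.05. The first count fell to 23, 16, 0 and 656 without WT, TKO, SKO and STKO, and the second to 110 without the 24 h arrays and 193 without the 48 h arrays.

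The smaller DMBA response of the arrays without STING was weighed first. Over 3683 genes called for DMBA the summed response without STING was 0.62 of that with STING (95% bootstrap interval over genes 0.61 to 0.64; genes are not independent replicates), and TKO over WT gave 1.03. Background correction and between-array normalization did not account for it, since the larger factor without background correction or with median scaling was again 0.62. The smaller sum was not confined to 1 genotype, since both lay below 1, SKO at 0.5 and STKO at 0.74. SKO and STKO also differ from each other. With 1 array per genotype and treatment, spread between cultures cannot be told from an effect of STING. A lower DMBA exposure of the cultures without STING was predicted to lower the aryl hydrocarbon receptor and NRF2 lists by about the factor of all genes. Only 1 dose was used, so how these lists follow exposure is not known, and the test cannot decide the question. Together the lists gave 1.05 (0.89 to 1.26), so their summed response was not smaller by that factor.

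That last result is weaker than its number, because it averages both times and both lists. The aryl hydrocarbon receptor list alone gave 0.89 (0.75 to 1.12) and 0.8 in SKO. Against its own DMSO array its median in SKO was below that in WT at 24 h (0.89 against 1.24) and above it at 48 h (2.14 against 1.59). Against WT under DMSO it was lower in SKO at both times (0.15 against 1.24 and 0.63 against 1.59). The NRF2 median was higher in SKO than in WT against its own DMSO array (0.65 against 0.43 and 2.16 against 1.95), but not against WT under DMSO (0.35 against 0.43 and 1.94 against 1.95), and each rests on 1 unreplicated DMSO array. A lower or slower exposure of SKO stays open. By list, over the members called for DMBA, the factor was 0.56 for p53 targets, 0.5 for cholesterol synthesis and 0.49 for NF-kB response genes. For the 581 called genes among the longest 10% of genes it was 0.52. It was 0.82 for mitosis (0.53 in SKO, 1.11 in STKO) and 1.16 for NRF2, so the response was not smaller for every list. A part of STING in the response to DMBA stays open as a hypothesis, as do differences between the cultures in growth or cell mix, which are confounded with genotype. The Y-linked Eif2s3y and Kdm5d were detected in WT alone, while TKO over WT gave 1.03 over the genes called for DMBA. These values argue against the presence of Y-linked transcripts as the source of the smaller response.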

How the results depend on the processing

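Leaving out the X and Y genes and the neighbours of the targeted genes was an alternative chosen after seeing the data, and the others were planned. No result reversed. Of the counts of called probes, 81 stayed within 1.5 times the reported count and 35 did not, 26 of these on leaving out a genotype or treatment.

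The Sting difference (1122 probes) depended on processing more than any other count: it was 1884 in the authors' table, 1885 without background correction, 2166 with a trended and robust variance and 211 without a detection filter. The cause was not tested. It was 1361 with median scaling, 777 with both interaction terms, 1115 at 24 h alone and 920 at 48 h alone. Requiring detection on all 12 arrays, which tests fewer probes and drops those absent in 1 genotype, gave 509 for TKO against WT, 754 for SKO against WT, 460 for STKO against TKO, 18 for STKO against SKO and 244 for the Trex1 effect with minus without STING.

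Leaving out 1 genotype in turn, which removes samples and degrees of freedom, gave 581 to 3464 probes for DMBA at 24 h, 4885 to 7268 at 48 h, 170 to 1617 for 48 against 24 h, 3670 to 6521 for the mean of both times, 0 to 656 for the Sting difference and 0 to 1 for the Trex1 difference. Leaving out 1 treatment gave 303 to 742 for TKO against WT, 208 to 2168 for SKO against WT, 294 to 996 for STKO against TKO, 9 to 74 for STKO against SKO and 110 to 469 for the Trex1 effect with minus without STING. In the response differences this leaves 1 genotype for a status, which is assumed to vary like the others.

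Of the 51 named genes called for the Sting difference 0 stayed called in every leave-one-out fit, although all 51 kept their sign. For DMBA at 48 h 86 of 96 stayed called in all, at 24 h 36 of 76, and for STKO against TKO 33 of 50. It was 77 of 94 for the mean of both times and 19 of 65 for 48 against 24 h. For TKO against WT it was 24 of 45, for SKO against WT 27 of 63 and for STKO against SKO 6 of 20. For the Trex1 effect with minus without STING it was 19 of 42. Median scaling changed the share of called probes that were higher from 50.1 to 69.1% for 48 against 24 h, from 47.8 to 30.6% for the Sting difference and from 43.4 to 32.3% for SKO against WT. For DMBA at 48 h it went from 48.3 to 57.4% and for the mean of both times from 48.3 to 53.7%, so which direction held more probes there depends on scaling. Of the gene list calls 78 were lost with an estimated correlation, so most of those given above did not hold with it. The other 164 list results kept their status there, called or not. On leaving out the member that changed most 15 calls were lost. Without that member 32 list results not called before changed direction and 2 gained a call. Signal over background limits the dim probes, and without a detection filter 113 named calls were lost.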

Other observations

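Of the tests in this part, the one without the X and Y genes and the neighbours of the targeted genes was chosen only after the result was seen. Relative to WT under DMSO, the median of the interferon-stimulated genes stood at 0.42, 0.99 and 1.55 in TKO under DMSO, 24 h and 48 h, at -2.13, -2.13 and -2.01 in SKO, and at -2.29, -2.18 and -2.06 in STKO. The genotypes without STING were thus already lower before DMBA, and 14 of the 41 genes were undetected on all of their arrays. Macrophage markers stood at -2.61, -2.98 and -2.80 in TKO on the same scale and between -0.50 and -1.39 in SKO and STKO. In TKO the interferon-stimulated median was thus highest where the macrophage markers were lowest. If the markers follow the share of macrophages, this argues against a larger share as the source of the higher transcripts in TKO. In SKO and STKO both lists stood below WT under DMSO, and whether a different share of macrophages contributed there was not tested. Of the named SKO to WT differences, Zfp330 was at least 46.8-fold lower on 1 probe (means 4.72 and 11.27, not well above background in SKO) and lower by 0.34 on the log2 scale on another, and no test here tells a change of the probed sequence from one of the gene's level. Without the X and Y genes and the neighbours of the targeted genes, 918 probes were called for TKO against WT.

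Long genes fell after DMBA at 24 h. Gene lengths in assembly GRCm38.p6 were available for 10129 tested genes (99.9%), and the 10 genes with the largest falls had a median length of 415 kb against 22.2 kb of all. Of 214 genes of at least 300 kb 65.9% were called lower and 0% higher (median -1.11), against 4 and 10% of 2699 genes under 10 kb. The 1013 longest genes, those from 112 kb, lay 0.48 below the rest (gap -0.48, 95% bootstrap interval over genes -0.52 to -0.44), and the gap was -0.42 at 48 h.

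Brightness of the probes was not the cause on its own, since the median gap within 5 classes of like brightness was -0.5. The gaps were -0.5, -0.56, -0.55, -0.39 and -0.31 from the dimmest to the brightest class, so it was smaller among bright probes. Background correction and between-array normalization could shrink the gap but left -0.37 as the smaller of the alternatives. The trend was seen in DMBA-treated against DMSO arrays of every genotype: Spearman's rho across genes between length and change at 24 h was -0.35 in WT, -0.34 in TKO, -0.26 in STKO and, highest, -0.13 in SKO, against 0 to -0.03 between DMSO arrays of different genotypes. Genes are not independent replicates. The cause was not tested. Time in culture stays open because the time of the DMSO cultures is not given, and RNA quality of the treated cultures because its measurements were not used here.

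Strain variants carried along with the targeted genes in this mixed background were tested among the 100 nearest named genes by Fisher's exact test, 2-sided, in 8 tests. Near Trex1 the larger exact p of the 2 comparisons was 0.384. In TKO against WT 8 of 100 were called there, where 5.78% of other genes were. In STKO against SKO 1 of 100 was called, Sema3f, where 0.15% of other genes were (exact p = 0.147). Near Sting1 the larger exact p was 0.823. Each gene was counted by its main probe alone, so a change on another probe did not enter. Near Trex1 14 of 100 were called in SKO against WT, which carries no Trex1 deletion (exact p = 0.0152, adjusted p = 0.122). These tests cannot exclude such variants.

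The real assignment of arrays was also compared with other splits. For the mean of both times 1 of 81 assignments of controls called as many probes, the real one with 6432, a share under 0.05. That share does not exclude chance, and it cannot tell DMBA from time in culture. The highest other, 5797, took the 48 h array as control in all 4 genotypes and so followed time. The remaining comparisons allow too few splits for a share under 0.05. For each DMBA time and for 48 against 24 h there were 8 splits, 1 of which, the real one, called as many, with 2876, 7277 and 1919 probes against a highest other of 0. For each of the 4 genotype comparisons there were 4, 1 of which called as many, with 958 (TKO against WT), 1203 (SKO against WT), 891 (STKO against TKO) and 34 (STKO against SKO) against a highest other of 0. For the Trex1 difference all 3 of 3 called as many as the real 0 (limma, 290 at an unadjusted p under 0.05), the highest other being 1122.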
